A study of Sus scrofa with 10 samples.

How the data were processed

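Total RNA from aortic valve leaflets of female swine was labelled with biotin and hybridised to the Affymetrix GeneChip Porcine Genome array, which reads transcripts with groups of short probes called probe sets. Of the 10 arrays, 3 came from juvenile wild-type (WT) swine, 3 from juvenile Rapacz familial hypercholesterolemic (RFH) swine and 4 from adult RFH swine. RFH swine are a breed with inherited high blood cholesterol. Juveniles were 3 months old and adults 2 years old. Per the labels all animals ate standard chow, and leaflets were put in RNAlater in the hour after death.

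The deposited table holds log2 expression values, 1 per probe set and array, for 24123 probe sets. The unit was read from the values, which ran from lowest values between 2.01 and 2.21 to highest values between 14.86 and 14.96. The submitters' processing notes name R 2.15.2. The methods of background correction, normalization and summarisation are not given in the sources used here. Array medians lay between 6.96 and 7.03, so the values had been normalized between arrays by the submitters. No detection calls were used, and no values were missing. For arrays the number per group, 3 or 4, limits the precision.

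The 124 Affymetrix control probe sets were left out of the comparisons and read separately, which left 23999 probe sets. Of these, 10069 carry exactly 1 gene symbol in the array annotation, 198 carry several and 13732 carry none. Where a gene had several probe sets, the probe set with the highest mean over the 10 arrays stood for it, which gave 6765 genes, 2261 of them with several probe sets. The gene IDs of 9989 annotation entries were found in the RefSeq gene table, and 0 of their symbols differed there.

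Group means were fitted to all 10 arrays at once with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes without an intensity trend), so that the 3 groups shared 1 estimate of the spread with 7 residual and 3.57 prior degrees of freedom. The contrasts were adult RFH minus juvenile RFH and juvenile RFH minus juvenile WT, and tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 23999 probe sets, and rose or fell is written for an adjusted p under 0.05. Standard errors (SE) are limma's moderated ones, and group values are means ± SD over arrays.

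The comparisons, the threshold, 39 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover matrix, mineralisation, signalling, lipid, inflammation, immune, endothelial, growth, stress and metabolic genes, with markers of other cell types a leaflet sample could hold. Lists with at least 5 measured genes, 38 of the 39, were tested with limma's camera at a preset correlation between genes of 0.01, and Benjamini-Hochberg adjusted over the lists. Camera asks whether a list's genes move more than all other genes. Camera was also run with a correlation estimated from the residuals, and limma's fry, which asks whether a list's genes move on balance in a given direction, was run beside it. Members were counted with adjustment over all probe sets and adjusted over the list alone.

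Genes were named by this rule, for probe sets with exactly 1 symbol. In each comparison the text could name the 8 genes with the largest rises and the 8 with the largest falls among called genes whose groups did not overlap. It could also name up to 3 called members per direction of each list with the smallest p, or the member with the smallest p where none was called. Named in any case, where measured, were genes that include APOE, RUNX2, SOX9, SPP1, ACTA2, COL1A1, MGP, VCAM1, MMP9, TGFB1, BMP2 and CD68. RUNX2, COL1A1, BMP2 and CD68 had no probe set with exactly 1 symbol and were not analysed here.

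The alternatives were quantile normalization, centring of each array on its median, cyclic loess, leaving out probe sets with a mean below the median of all probe sets, a fit of only the 2 groups compared, a variance prior with trend and robust estimates, array weights, the replicate number as a block, values below 4 raised to 4, each array left out in turn, 1 probe set per gene, an added fold threshold of 2, and for lists the mean of a gene's probe sets and the estimated correlation. A covariate for the difference between 3' and 5' control probe sets was added after the data were seen. Control probe sets were compared with exact two-sided permutation tests. In simulated data of the same size with 100 changed probe sets per fold size, the fit recovered 79% of changes of 1 and 96% of changes of 2 on the log2 scale with 9 false calls for adult against juvenile RFH, and 75% and 96% with 6 false calls for juvenile RFH against WT. The simulated noise was independent with the same spread in all 3 groups. In the data the median SD was 0.095 in juvenile WT, 0.125 in juvenile RFH and 0.188 in adult RFH arrays. The shares recovered and the false calls therefore check the fit and do not give its error rates on these data.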

Results

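Gene expression was measured in aortic valve leaflets of 3 juvenile WT, 3 juvenile RFH and 4 adult RFH swine, 10 arrays with 23999 probe sets. The median SD of a probe set over replicate arrays was 0.095 on the log2 scale in juvenile WT, 0.125 in juvenile RFH and 0.188 in adult RFH valves. The first principal component held 58.4% of the variance and parted the adult arrays, at 26.8 to 66.6, from the juvenile arrays, at -40.6 to -14.1. The median Pearson correlation across probe sets was 0.976 between adult and juvenile RFH arrays and 0.992 between juvenile RFH and juvenile WT arrays, and probe sets are not independent replicates. The p-values measure the spread between samples as labelled, and the labels do not state that each array came from a separate animal.

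The study compared adult with juvenile RFH leaflets and juvenile RFH with juvenile WT leaflets. The arrays' control probe sets were read first. The difference between 3' and 5' probe sets of actin, GAPDH and EF1A, which grows as RNA breaks down, averaged 2.24 ± 0.45 (SD, n = 4) on the log2 scale in adult RFH and 2.25 ± 0.14 (SD, n = 3) in juvenile RFH arrays (two-sided exact permutation p = 0.943). It averaged 2.09 ± 0.09 (SD, n = 3) in juvenile WT arrays, 0.16 below juvenile RFH (two-sided exact permutation p = 0.2). Of its 3 genes EF1A had the largest difference between juvenile RFH and WT, 1.53 ± 0.28 against 0.99 ± 0.12 (SD, n = 3 each), 0.54 higher without overlap (exact permutation p = 0.1, the smallest for 3 against 3). Actin differed by 0.13 and GAPDH by -0.18 (exact permutation p = 0.2 for each). The 12 poly-A control probe sets averaged 7.12 ± 0.16 in adult RFH, 6.32 ± 0.02 in juvenile RFH and 6.54 ± 0.06 in juvenile WT arrays. Adults lay 0.80 above juvenile RFH (exact permutation p = 0.0286, the smallest that 4 against 3 arrays allow), and juvenile RFH differed from WT by -0.22 (exact permutation p = 0.1, the smallest for 3 against 3). The hybridisation controls differed by 0.09 between adult and juvenile RFH (exact permutation p = 0.429) and by -0.01 between juvenile RFH and WT (exact permutation p = 1).

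Adult RFH leaflets differed from juvenile RFH leaflets by a rise of stress-response, inflammatory and lipid-handling genes and a fall of genes for the collagen and elastic matrix. By camera the immediate early and heat shock list held with an estimated correlation (adjusted p = 0.0134), and the inflammatory, lipid, collagen and elastic fibre lists were lost (adjusted p = 0.372, 0.519, 0.372 and 0.519 with an estimated correlation). IL6, a cytokine that drives the acute-phase response, had the largest rise among named genes, from 5.09 ± 0.33 (SD, n = 3) to 11.38 ± 0.48 (SD, n = 4) on the log2 scale, 77.9-fold. The chemokines CXCL14 and CXCL8 rose 23.5-fold and 16-fold, and FABP4, the fatty acid binding protein of adipocytes and macrophages, rose 14.2-fold. Single adult arrays weighed on these folds, which were 12.9 for CXCL14 without adult RFH replicate 2, and 10.3 for CXCL8 and 9.13 for FABP4 without adult RFH replicate 1. TNC, the matricellular glycoprotein tenascin-C, fell by 2.86 ± 0.25 (SE) on the log2 scale, and COL5A1, a chain of type V collagen, fell by 1.94 ± 0.22 (SE). In each of these genes every adult array lay on the same side of every juvenile RFH array, as the rule that chose them required.

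This comparison sets valves of 2-year-old against 3-month-old RFH swine, and with the 3 groups analysed here a change with age is not separated from 1 with the course of the disease. The labels give no scan date or batch, and the poly-A controls lay 0.80 higher in adults, so a batch that follows age cannot be tested and bears on every value of this comparison. Of the 23999 probe sets, 4025 passed the threshold in this comparison, 1927 up and 2098 down (7560 at an unadjusted p under 0.05), and 905 of them also changed at least 2-fold, 558 up and 347 down. By gene, 1305 of 6765 changed, 774 up and 531 down, and in 13 of these another probe set of the gene was called in the opposite direction. The groups did not overlap in 29.9% of genes, where chance gives 5.7%. The share of called probe sets that rose was 47.9%, and with arrays centred on their medians or cyclic loess it was 53.0% or 53.2%, so neither direction prevailed under every scaling. The count was 2243 without juvenile RFH replicate 1, 2280 without juvenile RFH replicate 3 and 2308 with only the RFH arrays in the fit. Of the 117 named genes called here, 77 stayed past the threshold whichever array was left out, and none changed direction.

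**Figure D1:**
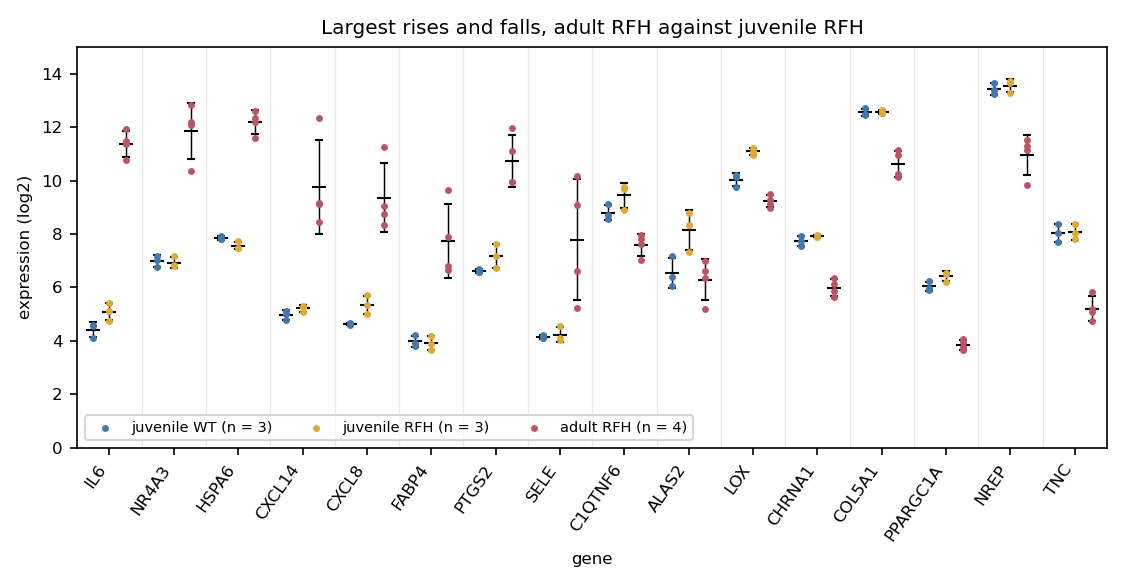
Log2 expression of the 8 named genes with the largest rises and the 8 with the largest falls between juvenile and adult RFH valves, with points for arrays and bars for the mean ± SD of juvenile WT (n = 3), juvenile RFH (n = 3) and adult RFH (n = 4). IL6 lies near 5.09 in juvenile RFH and near 11.38 in adult RFH arrays, and SELE spreads most within adults (SD 2.26).

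The immediate early and heat shock list, genes that cells switch on within minutes to hours of a stimulus, rose most. Of its 20 measured members 17 rose, 18 when adjusted over the list alone, none fell and 3 did not pass, with a median change of 2.18 (camera adjusted p = 4.32e-17, 0.0134 with an estimated correlation). The list's mean over members was 11.94 ± 0.08 in adult RFH, 9.92 ± 0.11 in juvenile RFH and 10.14 ± 0.11 in juvenile WT arrays, and all 20 members had positive changes. ATF3, a stress-induced transcription factor, rose by 3.47 ± 0.22 (SE, adjusted p = 1e-05), MYC by 3.37 ± 0.19 (adjusted p = 4.24e-06), IER3 by 2.49 ± 0.13 (adjusted p = 2.11e-06) and the orphan nuclear receptor gene NR4A3 by 4.94 ± 0.44 (adjusted p = 9.07e-05). Outside the list, HSPA6, a heat-inducible member of the HSP70 family, rose by 4.62 ± 0.20 (adjusted p = 5.36e-07). The poly-A controls moved with this list, 0.80 higher in adult RFH arrays, and the 3' to 5' difference did not, at -0.02.

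Inflammatory cytokine and chemokine genes rose as a group. Of 25 measured members 13 rose, 14 when adjusted over the list alone, and 12 did not pass, with a median change of 1.06 (camera adjusted p = 2.32e-07; adjusted p = 0.372 with an estimated correlation). SOCS3, a feedback inhibitor of cytokine signalling, rose by 2.61 ± 0.17 (SE, adjusted p = 1.3e-05) and the neutrophil chemokine CXCL2 by 1.84 ± 0.21 (adjusted p = 0.000445). PTGS2, the inducible cyclooxygenase, rose by 3.56 ± 0.43 (adjusted p = 0.000594). Both the list and the poly-A controls were higher in adult than in juvenile RFH. Among adult arrays they parted, since replicate 3 had the highest poly-A mean, 7.31, and the lowest list mean, 8.47. Between juvenile RFH and WT they parted too, with a mean change of 0.29 for the list and -0.22 for the poly-A controls. In juvenile RFH the group means of IL6, CXCL14, CXCL8 and SOCS3 were 5.09, 5.21, 5.35 and 4.40, under the array medians, so the size of their folds depends on the background that the submitters' processing left. The same limit holds for SELE (4.23), DLX5 (4.82) and TNFAIP6 (5.22) in juvenile RFH and for TNC (5.21), TGFBR3 (5.20) and AHSP (4.59) in adult RFH arrays.

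Markers of macrophages rose as well, with a median of 0.70 (camera adjusted p = 8.94e-05, and 0.519 with an estimated correlation). Of 19 measured members 12 rose over all probe sets and 13 adjusted over the list alone. The list's means in adult RFH replicates 1 to 4 were 10.32, 10.49, 9.80 and 9.84, against 9.44 to 9.46 in juvenile RFH arrays. The collagen list parted the same pairs of adult arrays, at 9.25, 9.26, 9.83 and 9.90. The immediate early list did not, at 11.99, 11.82, 11.95 and 12. Leaving out 1 array does not remove such a split, and its cause was not tested. TYROBP, a signalling adaptor of myeloid cells, rose by 1.29 ± 0.21 (SE), the endotoxin co-receptor CD14 by 0.92 ± 0.14 and the lysosomal membrane protein gene LAPTM5 by 1.06 ± 0.17, each with an adjusted p of 0.00329 or less. Of 16 complement genes 7 rose, and 10 rose and 1 fell when adjusted over the list alone, with a median of 0.43 (camera adjusted p = 0.00277; adjusted p = 0.153 with an estimated correlation). Complement component C2 rose by 2.03 ± 0.21 and C4A by 0.97 ± 0.19. Antigen presentation genes had a median of 0.42, with 3 of 19 called, 5 adjusted over the list alone (camera adjusted p = 0.0195; adjusted p = 0.631 with an estimated correlation). That call ended without juvenile RFH replicate 1 (adjusted p = 0.0603) and without adult RFH replicate 2 (adjusted p = 0.115), and the class I gene SLA-2 in it rose by 0.42 ± 0.09.

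The interferon response list did not pass (median -0.26, camera adjusted p = 0.109), with 2 of 19 members down, also 2 adjusted over the list alone. Without juvenile RFH replicate 2 it passed downward (median -0.44, adjusted p = 0.000172), and that array also held high cardiac muscle transcripts, with a list mean of 7.82 against 5.36 and 5.59 in the other juvenile RFH arrays. IFI44L changed by -0.60 ± 0.15 (SE, adjusted p = 0.0201), a call lost without juvenile RFH replicate 1 (0.0877) and without juvenile RFH replicate 3 (0.0855).

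Endothelial activation and flow response genes rose, 10 of 16 over all probe sets and 11 adjusted over the list alone, with a median of 0.97 (camera adjusted p = 7.95e-05; adjusted p = 0.372 with an estimated correlation). ICAM1, an adhesion molecule that binds leukocytes, rose by 1.94 ± 0.21 (SE, adjusted p = 0.000323), and KLF4, a transcription factor induced by laminar flow, by 0.95 ± 0.13 (adjusted p = 0.000972). E-selectin (SELE) rose by 3.55 ± 0.93 (adjusted p = 0.0255), a call lost without juvenile RFH replicate 1 (0.0854), 2 (0.0677) or 3 (0.0669) and without adult RFH replicate 4 (0.05). Its value was 2.75 without adult RFH replicate 1 and 4.40 without adult RFH replicate 3. VCAM1, another leukocyte adhesion molecule, changed by 0.43 ± 0.13 (adjusted p = 0.0474). Its call held only without adult RFH replicate 3, and leaving out juvenile RFH replicates 1, 2 and 3 gave 0.121, 0.105 and 0.12, adult RFH replicates 1, 2 and 4 gave 0.0936, 0.052 and 0.069, and juvenile WT replicates 1, 2 and 3 gave 0.0703, 0.0726 and 0.0722. Of 17 endothelial marker genes 5 rose and 1 fell, 8 and 1 adjusted over the list alone, with a median of 0.54 (camera adjusted p = 0.0165; adjusted p = 0.574 with an estimated correlation; 0.05 without adult RFH replicate 1). Thrombomodulin (THBD) rose by 1.58 ± 0.14 and von Willebrand factor (VWF) by 1.48 ± 0.27, and the transcription factor gene ERG fell by 0.43 ± 0.09.

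Genes of lipid uptake, storage and efflux rose, 9 of 20 with 1 down over all probe sets, and 14 with 1 down adjusted over the list alone (median 0.68, camera adjusted p = 6e-04; adjusted p = 0.519 with an estimated correlation). APOE, the apolipoprotein through which cells clear and release cholesterol, rose by 1.78 ± 0.28 (SE, adjusted p = 0.0028), FABP4 by 3.83 ± 0.58 (adjusted p = 0.00213) and APOA1 by 0.96 ± 0.14 (adjusted p = 0.0014). The FABP4 value was 3.19 without adult RFH replicate 1. FABP4 averaged 3.91 ± 0.26 in juvenile RFH arrays, near the low end of the scale, so its fold depends on background. Adipocyte markers moved with this list, 4 of 12 up with none down, also 4 adjusted over the list alone (median 0.21, camera adjusted p = 0.193), and FABP4 and LPL are on both lists. Antioxidant genes rose too, 9 of 22 with 1 down, and 11 with 1 down adjusted over the list alone (median 0.40, camera adjusted p = 0.00233; adjusted p = 0.519 with an estimated correlation). PRDX6, a peroxidase, rose by 0.93 ± 0.13, and GPX7, a peroxidase of the endoplasmic reticulum, fell by 1.28 ± 0.15. Of 8 senescence and ageing genes 3 rose and 1 fell, the same counts adjusted over the list alone (median 0.28, camera adjusted p = 0.0165; adjusted p = 0.307 with an estimated correlation; median 0.17 without juvenile RFH replicate 1). CDKN1A, an inhibitor of the cell cycle, rose by 2.53 ± 0.18 and LMNA, which encodes the nuclear lamins A and C, by 1.22 ± 0.12, and IL6 is also on that list.

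Of 13 genes for fibrillar and associated collagens and their processing 9 fell, 10 adjusted over the list alone, none rose and 4 did not pass, with a median of -0.87 (camera adjusted p = 4.12e-07; adjusted p = 0.372 with an estimated correlation). COL4A2, a chain of basement membrane collagen, fell by 1.61 ± 0.24 (SE, adjusted p = 0.00201) and SERPINH1, the collagen chaperone, by 0.96 ± 0.12 (adjusted p = 0.000904). Of 7 elastic fibre genes 4 fell and 1 rose, the same counts adjusted over the list alone (median -0.91, camera adjusted p = 0.0151; adjusted p = 0.519 with an estimated correlation). LOX, the enzyme that cross-links collagen and elastin, fell by 1.87 ± 0.15 and the microfibril gene MFAP2 by 1.03 ± 0.22. Matricellular and adhesion genes had 5 of 12 down and 2 up, 8 and 2 adjusted over the list alone (median -0.34, camera adjusted p = 0.00502; adjusted p = 0.519 with an estimated correlation). NID2, a basement membrane protein, fell by 1.72 ± 0.22, and the fibronectin receptor chain ITGA5 rose by 1.51 ± 0.24.

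Among proteoglycan and hyaluronan genes 3 of 13 fell and 2 rose, 6 and 2 adjusted over the list alone, and the list did not pass (median -0.62, camera adjusted p = 0.1; 0.0237 without adult RFH replicate 3). HAPLN1, which links proteoglycans to hyaluronan, fell by 1.13 ± 0.17 (SE), asporin (ASPN) fell by 1.07 ± 0.15, and TNFAIP6, a hyaluronan-binding protein induced by inflammation, rose by 2.16 ± 0.29. Matrix proteases and inhibitors also did not pass as a list (median 0, camera adjusted p = 0.493), with 4 of 17 up and 1 down, 5 and 2 adjusted over the list alone. The metalloprotease inhibitor TIMP1 rose by 1.97 ± 0.19 and the urokinase gene PLAU rose 2.82-fold, while MMP9 had a change of -0.08 (adjusted p = 0.629). Wnt signalling genes fell, 6 of 11 with 1 up over all probe sets, and 7 with 1 up adjusted over the list alone (median -0.51, camera adjusted p = 0.00277; adjusted p = 0.372 with an estimated correlation). The Wnt co-receptor gene LRP6 fell by 0.99 ± 0.12 and the transcription factor gene LEF1 by 0.87 ± 0.17.

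The osteogenic list did not pass (median 0.04, camera adjusted p = 0.991), with 2 of 14 members up and 1 down, the same adjusted over the list alone. DLX5, a transcription factor of bone formation, rose by 2.58 ± 0.55 (SE, adjusted p = 0.0109). SPP1, which encodes osteopontin, changed by 1.28 ± 0.39 (adjusted p = 0.0467). Its adjusted p was 0.168 and 0.137 without juvenile RFH replicate 1 or 2, 0.101 and 0.0885 without adult RFH replicate 1 or 2, and 0.0686, 0.0698 and 0.0702 without juvenile WT replicate 1, 2 or 3. Chondrogenic genes had a median of -0.45 with 1 of 10 up and 2 down, the same adjusted over the list alone (camera adjusted p = 0.0628). That list passed without juvenile RFH replicate 2 (0.0392) or 3 (0.0312) and without adult RFH replicate 3 (0.00857) or 4 (0.0312). SOX9, the main transcription factor of cartilage, rose by 1.04 ± 0.27 (adjusted p = 0.0263), a call lost without juvenile RFH replicate 1 (0.0615), 2 (0.061) or 3 (0.1). Mineralisation inhibitors had 1 of 5 up, also 1 adjusted over the list alone (median 0.14, camera adjusted p = 0.519), with a rise of GAS6 by 0.45 ± 0.09 and a change of MGP, the matrix Gla protein, of -0.08 (adjusted p = 0.519; 0.07 with quantile normalization). MGP lay at 14.62 to 14.79 in all 10 arrays, near the arrays' highest values of 14.86 to 14.96, where a difference can be missed.

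Contractile genes of myofibroblasts and smooth muscle had 2 of 13 down, also 2 adjusted over the list alone (median -0.13, camera adjusted p = 0.181; 0.0493 without adult RFH replicate 3). ACTA2, smooth muscle actin, fell by 1.00 ± 0.21 (SE, adjusted p = 0.0103; 0.0507 without juvenile RFH replicate 1). TGF-beta and BMP signalling genes went both ways, 4 of 14 up and 3 down, 4 and 5 adjusted over the list alone (median 0.16, camera adjusted p = 0.744). TGFB1 rose by 1.42 ± 0.20 (adjusted p = 0.00147) and the co-receptor gene TGFBR3 fell by 0.95 ± 0.17 (adjusted p = 0.00473). Cell cycle genes had 4 of 34 down and 2 up, the same adjusted over the list alone (median -0.22, camera adjusted p = 0.0165; adjusted p = 0.631 with an estimated correlation; without juvenile RFH replicate 2 median -0.13 and adjusted p = 0.231). Cyclin B1 (CCNB1) fell by 1.23 ± 0.29, and CKS2, a subunit of cyclin-dependent kinases, rose by 1.72 ± 0.22.

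Cardiac and striated muscle markers had a median of -0.54 with none of 20 called by limma over all probe sets or adjusted over the list alone, and 1 up and 2 down at an unadjusted p under 0.05. The list passed (camera adjusted p = 0.0486; adjusted p = 0.631 with an estimated correlation) and depended on juvenile RFH replicate 2, without which its median was 0.01 and its adjusted p 0.973. The median was -0.87 without juvenile RFH replicate 1 and -0.83 without juvenile RFH replicate 3. It also ended without adult RFH replicate 1 (0.0732), 2 (0.0541), 3 (0.108) or 4 (0.0582). Of 4 erythroid markers, too few for the list test, 2 fell and all 4 did so adjusted over the list alone (median -1.05). AHSP, a chaperone of alpha globin, fell by 1.70 ± 0.35 (SE, adjusted p = 0.0088), and ALAS2, which starts haem synthesis in red cell precursors, changed by -1.86 ± 0.45 (adjusted p = 0.0183; 0.0715 without juvenile RFH replicate 1 and 0.0678 without juvenile RFH replicate 2). Outside the lists, NREP fell by 2.60 ± 0.34, and PPARGC1A, a coactivator of mitochondrial genes, fell by 2.57 ± 0.13 to a level of 3.85 in adults, where background weighs on the fold. CHRNA1, a subunit of the muscle acetylcholine receptor, fell by 1.92 ± 0.16 and C1QTNF6 fell by 1.85 ± 0.26.

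In all, 16 of the 38 lists passed, 10 up and 6 down, 12 of them whichever array was left out. With an estimated correlation 1 passed, the immediate early and heat shock list, and fry called 22, of which 13 were also called by camera. Of the 35 ways to split the 7 RFH arrays into groups of 4 and 3, 5 including the real one gave at least 16 called lists.

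**Figure D2:**
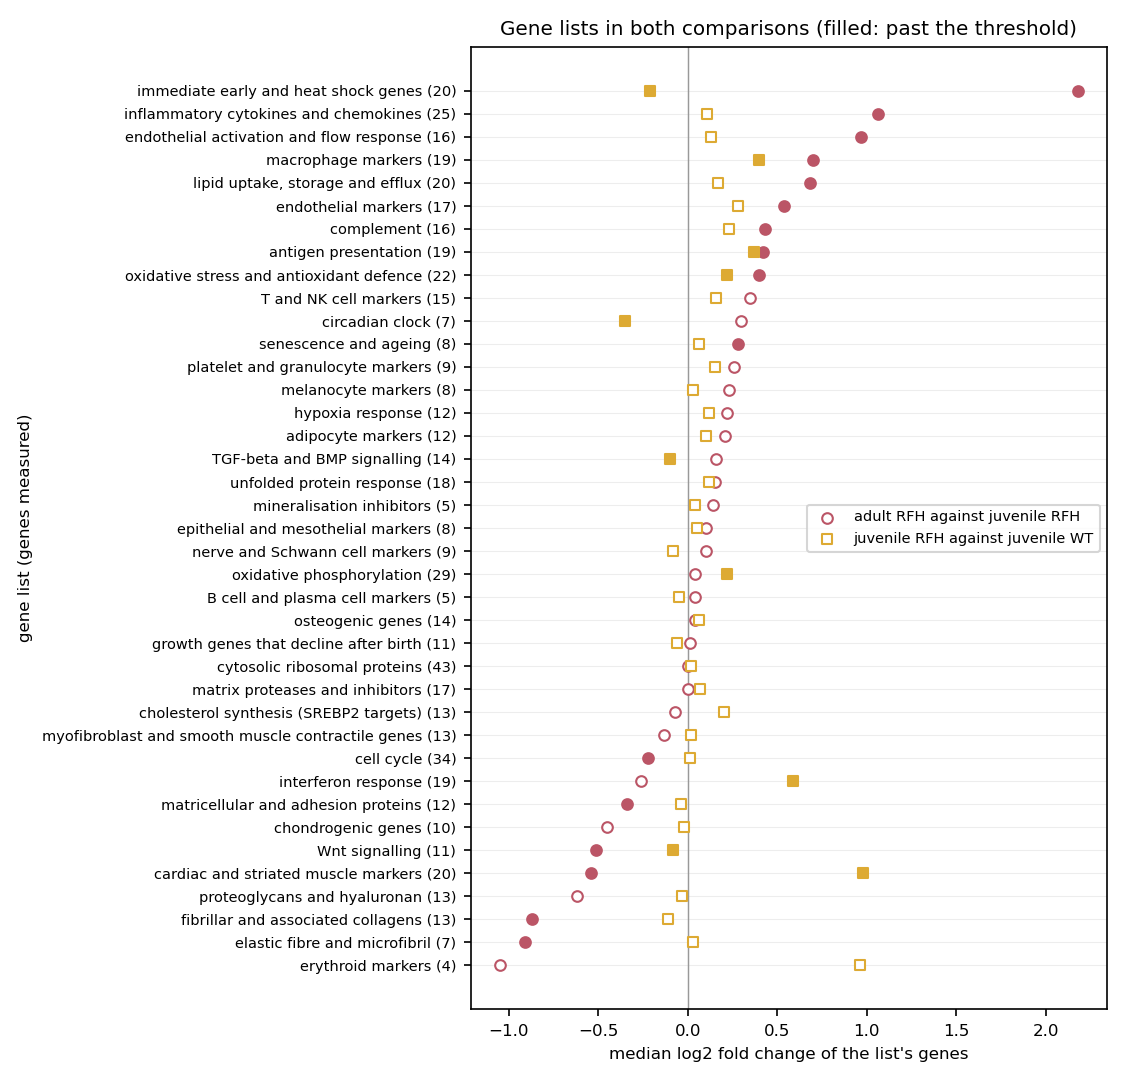
Median log2 fold change of the measured genes of each of the 39 lists (number measured in brackets) in adult against juvenile RFH valves (circles) and in juvenile RFH against juvenile WT valves (squares), filled where camera at the preset correlation passed. The immediate early and heat shock list lies at 2.18 in adults and at -0.21 in juveniles, and the erythroid list, with 4 genes, was not tested.

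The comparison of juvenile RFH with juvenile WT leaflets asks what differs at 3 months of age. RFH is a breed, so other differences between RFH and WT swine cannot be told apart here from those of high cholesterol. With no scan date or batch in the labels and sample numbers of the WT arrays that do not follow on from those of the RFH arrays, a batch that follows breed cannot be tested here. The antiviral gene OAS1, an interferon-induced sensor of double-stranded RNA, rose from 5.68 ± 0.46 (SD, n = 3) in WT to 8.15 ± 0.22 (SD, n = 3) in RFH valves, 5.54-fold. Its WT mean lay under the array medians, so the size of this fold depends on background. Interferon response genes were higher as a list by camera at its preset correlation (adjusted p = 2.94e-05; adjusted p = 0.78 with an estimated correlation), with positive changes in 19 of 19 measured members, of which 1 was called. At the preset correlation camera also called oxidative phosphorylation genes higher (median 0.22; adjusted p = 0.78 with an estimated correlation) and immediate early and heat shock genes lower (median -0.21; adjusted p = 0.372 with an estimated correlation), with no member of either called by limma (11 and 5 at an unadjusted p under 0.05). LOX, the cross-linking enzyme that fell in adults, rose 2.08-fold in juvenile RFH over WT.

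By probe set, 28 of 23999 passed the threshold, 12 up and 16 down (3047 at an unadjusted p under 0.05), of which 11 carry 1 symbol and 16 carry none. Of 6765 genes 9 were called, 6 up and 3 down, and the groups did not overlap in 35.8% of genes, where chance gives 10%. The count followed single arrays closely, with 2 calls without juvenile RFH replicate 3, 12 without juvenile RFH replicate 2, 6, 3 and 15 without juvenile WT replicate 1, 2 or 3, and 71 and 50 without adult RFH replicate 2 or 3. It also followed the fit, with 872 calls when only the 6 juvenile arrays were fitted and 1171 with array weights, and each of these included all 28. With dim probe sets left out it was 6, with low values raised to 4 it was 10, and with the replicate block it was 17.

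Among the 28 called probe sets the largest rise (2.65 on the log2 scale) and the largest fall (-4.39) were in probe sets without a symbol. The 9 called genes were each read by their brightest probe set. Among them OAS1 rose most (2.47 ± 0.25, SE, adjusted p = 0.00816, and 0.063 without juvenile RFH replicate 3). The other rises were in PGA5, CR1, CLEC3B, LOX and LPCAT3. The pepsinogen gene PGA5 rose by 2.09 ± 0.23 (adjusted p = 0.0112; 0.063 without juvenile RFH replicate 3, 0.0751 and 0.0856 without juvenile WT replicate 1 or 2). The complement receptor gene CR1 rose by 1.69 ± 0.25 (adjusted p = 0.0485), and the phospholipid-remodelling gene LPCAT3 by 0.72 ± 0.11 (adjusted p = 0.0485). CLEC3B, which encodes tetranectin, rose by 1.16 ± 0.18 (adjusted p = 0.0488) and LOX by 1.06 ± 0.16 (adjusted p = 0.0485). Among these genes the falls were in AKAP11, SYNE1 and RBM3. AKAP11, an anchor of protein kinase A, fell by 1.28 ± 0.16 (adjusted p = 0.0218). The nuclear envelope gene SYNE1 fell by 1.24 ± 0.19 (adjusted p = 0.0485). RBM3, an RNA-binding protein induced by cold, fell by 0.82 ± 0.13 (adjusted p = 0.0488). AKAP11 and SYNE1 averaged 4.29 and 3.88 in juvenile RFH arrays, where background weighs on the fold. The same limit holds for OAS1 and PGA5, which averaged 5.68 and 5.71 in WT arrays.

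All 9 calls were lost in at least 1 of the 10 fits that left out an array, and none reversed. Without juvenile RFH replicate 2 the adjusted p was 0.12 for CR1, 0.143 for CLEC3B and LPCAT3, 0.102 for LOX, 0.0621 for AKAP11, 0.155 for SYNE1 and 0.149 for RBM3. Without juvenile RFH replicate 3 the same 7 genes had 0.121, 0.182, 0.164, 0.179, 0.0927, 0.063 and 0.19 in the order CR1, CLEC3B, LPCAT3, LOX, AKAP11, SYNE1 and RBM3. Without juvenile WT replicate 1 they ranged from 0.092 for AKAP11 to 0.252 for CLEC3B, and without juvenile WT replicate 2 from 0.164 for AKAP11 to 0.245 for RBM3. Without juvenile WT replicate 3 all but CR1 were lost, from 0.0878 for AKAP11 and RBM3 to 0.11 for CLEC3B and LOX. Without juvenile RFH replicate 1 all but CR1 were lost too, from 0.0588 for AKAP11 to 0.096 for CLEC3B, LPCAT3 and SYNE1. Without adult RFH replicate 4 all but AKAP11 were lost, at 0.0643 for CR1 and SYNE1 and 0.0658 for CLEC3B, LPCAT3, LOX and RBM3, and CR1 was also lost without adult RFH replicate 1 (0.0567).

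**Figure D3:**
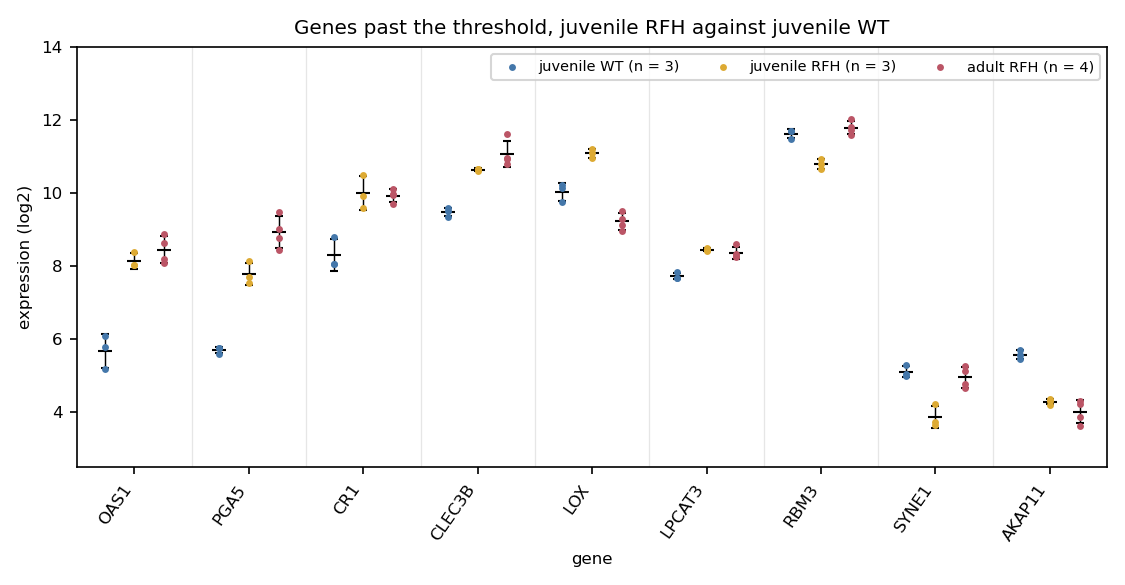
Log2 expression of the 9 genes called between juvenile RFH and juvenile WT valves, with points for arrays and bars for the mean ± SD of juvenile WT (n = 3), juvenile RFH (n = 3) and adult RFH (n = 4). OAS1 averages 5.68 in WT, 8.15 in juvenile RFH and 8.45 in adult RFH valves, and LOX averages 10.04, 11.09 and 9.23.

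Interferon response genes gave the smallest list p. Their mean was 9.30 ± 0.41 (SD, n = 3) in juvenile RFH and 8.61 ± 0.18 (SD, n = 3) in juvenile WT arrays, with a median change of 0.59 (camera adjusted p = 2.94e-05; adjusted p = 0.78 with an estimated correlation). Of 19 members 1 rose over all probe sets and 6 adjusted over the list alone. The juvenile RFH arrays differed among themselves, at 9.43, 8.84 and 9.63 in replicates 1, 2 and 3, against 8.48, 8.54 and 8.81 in WT. The oxidative phosphorylation list had positive changes in 28 of 29 members, with none called by limma over all probe sets or adjusted over the list alone and 11 up at an unadjusted p under 0.05 (camera adjusted p = 0.000197; adjusted p = 0.78 with an estimated correlation). Its most significant member COX5B, a subunit of cytochrome c oxidase, had a change of 0.41 ± 0.12 (SE, adjusted p = 0.192). Immediate early and heat shock genes had negative changes in 16 of 20 members, none called over all probe sets or adjusted over the list alone and 4 down and 1 up at an unadjusted p under 0.05 (camera adjusted p = 0.000197; adjusted p = 0.372 with an estimated correlation). These 3 list calls held whichever array was left out, and the poly-A controls, at -0.22, moved with the immediate early genes. The EF1A 3' to 5' difference was 0.54 higher in juvenile RFH, the same direction as the interferon and oxidative phosphorylation lists. Array by array it did not follow the interferon list, at 1.21, 1.68 and 1.70 in juvenile RFH replicates 1, 2 and 3. Among adult arrays the oxidative phosphorylation mean was highest, 11.19, in replicate 1, where EF1A was lowest, 1.29. It was lowest, 10.80, in adult RFH replicate 3, where EF1A was highest, 2.63.

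Cardiac muscle markers had a median of 0.98, and of 0.17 without juvenile RFH replicate 2 (camera adjusted p = 0.00696; adjusted p = 0.78 with an estimated correlation), with a mean of 6.26 ± 1.36 in juvenile RFH and 5.25 ± 0.03 in WT arrays. None of the 20 members was called by limma over all probe sets or adjusted over the list alone, 3 were up at an unadjusted p under 0.05, and without juvenile RFH replicate 2 the list did not pass (0.123). The 4 erythroid markers had a median of 0.96 with 0 called by limma over all probe sets, 3 up at an unadjusted p under 0.05 and 3 adjusted over the list alone, and AHSP had a change of 1.65 ± 0.37 (SE, adjusted p = 0.121).

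Macrophage markers were higher as a list, with a median of 0.40 and positive changes in 18 of 19 (camera adjusted p = 0.0171; adjusted p = 0.78 with an estimated correlation; 0.0783 without juvenile RFH replicate 1). None of them was called by limma over all probe sets, 5 were up at an unadjusted p under 0.05 and 4 adjusted over the list alone, with C1QA, a chain of complement C1q, at 0.81 ± 0.19 (SE, adjusted p = 0.139). Antigen presentation genes were higher as a list, with a median of 0.37 (camera adjusted p = 0.0171; adjusted p = 0.78 with an estimated correlation), lost without juvenile RFH replicate 3 (0.149) and without juvenile WT replicate 2 (0.0663). Antioxidant genes had a median of 0.22 (camera adjusted p = 0.0353; adjusted p = 0.78 with an estimated correlation), lost without juvenile RFH replicate 3 (0.101) and without juvenile WT replicate 2 (0.0615). In these 2 lists 0 members were called by limma over all probe sets or adjusted over the list alone, with 7 and 8 up at an unadjusted p under 0.05. The EF1A 3' to 5' difference, 0.54 higher in juvenile RFH, differed between the groups in the same direction as the macrophage, antigen presentation and antioxidant lists too.

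Lists with small negative medians were TGF-beta and BMP signalling, Wnt signalling and the circadian clock. The TGF-beta list had a median of -0.10 (camera adjusted p = 0.0249; adjusted p = 0.372 with an estimated correlation; 0.0587 without juvenile RFH replicate 3). That median was -0.01, -0.18 and -0.06 without juvenile RFH replicate 1, 2 or 3, and -0.06 without juvenile WT replicate 2. The Wnt list had a median of -0.08 (camera adjusted p = 0.0434; adjusted p = 0.78 with an estimated correlation) and was lost without juvenile RFH replicate 2 (0.105) or 3 (0.0994), adult RFH replicate 1 (0.0535) and juvenile WT replicate 2 (0.117), with medians of -0.05 without juvenile RFH replicate 2 and -0.04 without juvenile WT replicate 2. The clock list had a median of -0.35 (camera adjusted p = 0.0434; adjusted p = 0.78 with an estimated correlation) and was lost without juvenile RFH replicate 2 (0.105) or 3 (0.0994), adult RFH replicate 4 (0.0513) and juvenile WT replicate 2 (0.107) or 3 (0.0794). No member of these 3 lists was called by limma over all probe sets, 4, 1 and 2 were down and 1, 0 and 1 up at an unadjusted p under 0.05, and adjusted over the list alone 1 TGF-beta member was up and 1 down.

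In all, 10 of the 38 lists passed, 6 up and 4 down, none with an estimated correlation (2 at an unadjusted p under 0.05) and none by fry (8 at an unadjusted p under 0.05). Without juvenile RFH replicate 3 the number was 5. Collagens had a median of -0.11 (camera adjusted p = 0.0568), and that list passed without juvenile RFH replicate 1 (0.0135), adult RFH replicate 2 (0.0393) and juvenile WT replicate 2 (0.0486) or 3 (0.0243). The cell cycle list (median 0.01, camera adjusted p = 0.136) passed downward without juvenile RFH replicate 2 (median -0.19, adjusted p = 4.39e-06) and without juvenile WT replicate 2 (median -0.07, adjusted p = 0.0303) or 3 (median -0.05, adjusted p = 0.0242).

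Of the measured genes named in any case none passed between juvenile RFH and WT, and neither did ENPP1. SPP1 had a difference of 1.54 ± 0.42 (SE, adjusted p = 0.174), VCAM1 of 0.60 ± 0.14 (adjusted p = 0.134) and ENPP1, which makes the mineralisation inhibitor pyrophosphate, of 0.65 ± 0.14 (adjusted p = 0.118). In the fit of the 6 juvenile arrays alone their adjusted p-values were 0.0362, 0.0157 and 0.0357. The difference was 0.31 ± 0.30 for APOE (adjusted p = 0.736), 0.23 ± 0.23 for ACTA2 (adjusted p = 0.738) and -0.45 ± 0.29 for SOX9 (adjusted p = 0.572). It was -0.07 ± 0.22 for TGFB1 (adjusted p = 0.931), 0.04 ± 0.08 for MGP (adjusted p = 0.874), whose probe set was near the top of the scale, and 0.08 ± 0.11 for MMP9 (adjusted p = 0.835).

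Both comparisons share the juvenile RFH arrays with opposite sign, so noise alone makes their fold changes run against each other. Across probe sets the Pearson correlation of the changes was 0.032 with a covariance of 0.0039, while 100 simulations of unchanged groups gave a mean correlation of -0.535 (range -0.562 to -0.512) and a covariance of -0.018. The simulated noise was independent over probe sets with the same spread in all groups. In the data the median SD was 0.125 in juvenile RFH and 0.188 in adult RFH arrays. The simulations therefore show the direction of the shared-array effect and not its size, and nothing is concluded from the gap to 0.032. Of the 28 probe sets called between juvenile RFH and WT, 11 were also called in adults. PGA5 rose in both, 0 fell in both, 7 rose in adults after being lower in juvenile RFH than in WT, among them RBM3 and SYNE1, and 3 fell after being higher, among them LOX. Unrelated calls would give 0.964 up in both, 1.4 down in both, 1.28 up in adults only after a fall and 1.05 the other way. Those numbers ignore the shared arrays, which favour the opposite-direction counts, and no expected number that allows for them was computed. In 24 of the 28 the adult mean lay on the same side of the WT mean as the juvenile RFH mean, a count that shares the WT arrays with the calls. With dim probe sets left out, 4 probe sets were called in both.

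**Figure D4:**
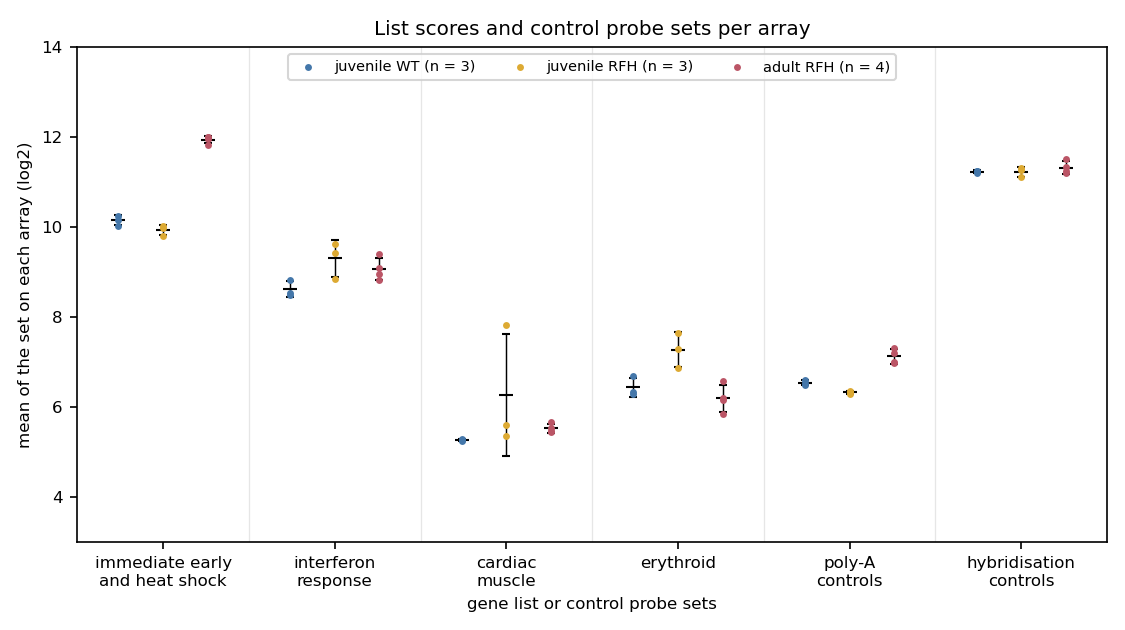
Mean log2 expression per array over the measured members of 4 gene lists and over the poly-A and hybridisation control probe sets, with points for arrays and bars for the mean ± SD of juvenile WT (n = 3), juvenile RFH (n = 3) and adult RFH (n = 4). Juvenile RFH replicate 2 stands at 7.82 in the cardiac list, and adult RFH arrays average 11.94 in the immediate early and heat shock list and 7.12 in the poly-A controls.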

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

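The tests of the immediate early list, the cardiac markers and the control probe sets in this part were chosen after the results were seen.

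In 9 of 156 named genes, 0 of 39 list means and 0 of 6 control measures 1 adult RFH array stood far from the other 3 by Dixon's test, where chance gives about 1 in 20. Dixon's test looks for 1 array apart from the other 3, so it misses adult arrays that part in pairs. Adult RFH replicate 1 held ADAMTS1 at 12.39 (others 13.49 to 13.55) and CIDEA at 7.5 (7.19 to 7.22). Adult RFH replicate 2 held HIF1A at 12.53 (12.21 to 12.26), ID1 at 12.14 (11.42 to 11.44) and MITF at 7.24 (6.68 to 6.73). Adult RFH replicate 3 held GLB1 at 10.30 (10.11 to 10.13). Adult RFH replicate 4 held CD59 at 12.32 (12.14 to 12.16), FASN at 9.51 (9.43 to 9.44) and LRP6 at 8.34 (7.92 to 7.98). The poly-A control probe sets, which the comparisons of genes do not use, lay 0.80 higher in adult than in juvenile RFH arrays.

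The mean of the immediate early and heat shock genes was higher in all 4 adult RFH arrays than in all 6 juvenile arrays. RNA degradation as the whole cause is argued against, since 3 of the 4 adult arrays had a 3' to 5' control difference no higher than the highest juvenile RFH array, and their lowest list mean still lay 1.81 above the highest juvenile RFH one. In the normalized values a shift common to genes of the same level is argued against as well, since the highest median among 10000 random lists matched on expression was 0.35. The values had been normalized between arrays, so such lists centre near 0, at a median of 0.01. The test therefore cannot speak to the cause of the poly-A difference, which stayed at 0.80 after normalization. Tissue handling, such as the time before preservation, stays open and cannot be told apart from age, since the lowest adult list mean lay 1.57 above the highest juvenile one and no array lay over 0.13 from its group's mean. Age, the course of the disease and a batch that follows age also stay open and were not tested, since the arrays include no adult WT group and the labels give no scan date or batch.

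Cardiac muscle markers were high in juvenile RFH replicate 2. Of 20 markers 14 had their highest value of all 10 arrays there, where chance gives 2 on average and seldom more than 5, and the abundant contractile genes ACTC1, MYH7, TNNT2 and MYL2 stood at 10.89, 10.59, 8.63 and 10.94 against at most 5.91, 5.84, 3.76 and 6.13 elsewhere. Heart muscle carried over into that sample is a candidate explanation, as a hypothesis. None of the 20 markers is on another list, and none lay above the median of all genes in WT arrays. Array brightness or normalization is argued against, since the markers' median deviation there was 2.33 and the highest among 10000 matched random lists was 0.21.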

How the results depend on the processing

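The covariate for the 3' to 5' control difference was chosen after the data were seen, and the other alternatives were planned.

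For adult against juvenile RFH, 76 of 117 named gene calls held in every alternative that tested the gene, and 41 were lost in at least 1. None reversed, and 2 of the 5 named genes not called passed in some. With dim probe sets left out, 92 of the 122 named genes and 30 of the 38 lists were tested. Of the 16 list calls 1 held in every alternative, the immediate early and heat shock list (medians 2.00 to 2.29, adjusted p at most 0.0134), and 8 lists not called passed in some. For juvenile RFH against WT none of the 9 gene calls or 10 list calls held in every alternative, none reversed, and 21 genes and 3 lists not called passed in some.

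The 4025 probe sets of adult against juvenile RFH became 2308 with only the RFH arrays, 1425 with 1 probe set per gene and 905 with a fold of at least 2, each of which tests fewer arrays, fewer probe sets or a narrower criterion. Leaving out an array gave 2243 to 4965. The 28 of juvenile RFH against WT became 872 with only the juvenile arrays, 1171 with array weights, 62 with the control covariate, 17 with the replicate block, 10 with low values raised, 6 with dim probe sets left out and 12 with 1 probe set per gene. Leaving out an array gave 2 to 71. A fit of only the 2 groups compared leaves each difference between group means as it was. The 872 and the 2308 therefore came through the estimate of the spread and its degrees of freedom. For the other alternatives the cause was not tested. The median SD of a probe set was 0.188 in adult and 0.095 in WT arrays. Array weights ran from 0.43 to 0.95 in adults and from 1.64 to 2.51 in WT.

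List calls for adult against juvenile RFH fell from 16 to 1 with an estimated correlation and ran from 14 to 18 when an array was left out. For juvenile RFH against WT the 10 became 0 by camera with an estimated correlation and 4 of 30 with dim probe sets left out, and ran from 5 to 12 when an array was left out. The cardiac list of adult against juvenile RFH ran from -0.87 without juvenile RFH replicate 1 to 0.01, a reversed sign, without juvenile RFH replicate 2, the array in which its markers were highest. Probe sets called in both comparisons numbered 4 with dim probe sets left out, where fewer were tested. The cause was not tested.

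The labels do not say what the replicate numbers mean, and the values gave no clear sign that the numbers pair the samples. Correlations of deviations between juvenile and adult RFH arrays of the same number were -0.16, 0.16 and 0.09, and between juvenile RFH and WT arrays 0.19, -0.01 and -0.07. With the number as a block the probe sets called were 3922 and 17 and the lists 20 and 9. Among arrays, signal over background limits the dim genes, and no detection calls were used.

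Other splits of the arrays were counted as well. For adult against juvenile RFH 1 of 35 splits, the real one, gave as many as the 4025 probe sets, and the highest other gave 1603. The real split is always 1 of them, so this is the smallest share that 35 splits allow. Splits that mix ages carry the group difference into the spread, which lowers their counts. A batch or handling that follows age would give the same result. For the 16 lists chance was not excluded, since 5 of 35 splits gave as many and the highest other gave 18. Some of these splits keep most juvenile arrays together and so hold part of the age difference. The list counts therefore cannot decide whether chance alone would give as many. The 10 splits of the 6 juvenile arrays are too few for a share under 0.05. There the real split gave 28 probe sets and the highest other 0, with only the juvenile arrays 872 and 0, and 10 lists and 6, so in each case 1 split gave as many.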

Other observations

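The correlations with erythroid markers in this part were chosen after the results were seen.

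Between juvenile and adult RFH valves, lists that did not pass as a whole still held called genes. Of all 6765 genes 1305 were called, so most lists hold some in any case. In the clock list (median 0.30, camera adjusted p = 0.17) 2 of 7 rose and 1 fell, also 2 and 1 adjusted over the list alone, with the repressors NFIL3 up by 2.94 ± 0.21 (SE) and BHLHE40 by 2.28 ± 0.27. ARNTL, the clock activator, fell by 1.01 ± 0.22 (adjusted p = 0.0127; 0.0565 without juvenile RFH replicate 3). Of 18 unfolded protein response genes 6 rose and 2 fell, 7 and 2 adjusted over the list alone (median 0.15, adjusted p = 0.159), with the chaperone gene DNAJB9 up by 1.05 ± 0.16 and the stress transcription factor DDIT3 by 0.85 ± 0.14. Of 12 hypoxia genes 3 rose and 1 fell, the same adjusted over the list alone (median 0.22, adjusted p = 0.219), with the glycolytic enzyme ENO1 up by 0.69 ± 0.12. Of 13 cholesterol synthesis genes 2 rose, also 2 adjusted over the list alone, INSIG1, which restrains sterol synthesis, by 1.64 ± 0.18 and the synthesis enzyme HSD17B7 by 1.38 ± 0.09, while the median was -0.07, the mean 0.16 and camera's direction up (adjusted p = 0.615). Of 12 adipocyte markers 4 rose, also 4 adjusted over the list alone (median 0.21, adjusted p = 0.193), among them CIDEA, a lipid droplet protein, by 0.85 ± 0.11.

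Among cell type lists, 4 of 9 nerve and Schwann cell markers rose, 4 with 1 down adjusted over the list alone (median 0.10, adjusted p = 0.148; median 0.21 and adjusted p = 0.0403 without adult RFH replicate 2), with the neuronal hydrolase UCHL1 up by 1.47 ± 0.22 (SE). Of 9 platelet and granulocyte markers 1 rose, also 1 adjusted over the list alone, the neutrophil protein S100A9 by 2.74 ± 0.49 from a dim 4.53 in juvenile RFH (list median 0.26, adjusted p = 0.12; 0.0225 without adult RFH replicate 4). Of 15 T and NK cell markers limma called 0, also adjusted over the list alone, with 1 at an unadjusted p under 0.05 (median 0.35, adjusted p = 0.17). B and plasma cell markers had a median of 0.04 (1 of 5 up, 2 with 1 down adjusted over the list alone, adjusted p = 0.744), melanocyte markers 0.23 (1 of 8 up, 0 adjusted over the list alone, adjusted p = 0.227) and epithelial markers 0.10 (0 of 8 called by limma, 0 at an unadjusted p under 0.05, adjusted p = 0.387). Oxidative phosphorylation genes had a median of 0.04 (1 of 29 up and 1 down, 1 and 0 adjusted over the list alone, adjusted p = 0.6), with cytochrome c (CYCS) up by 1.75 ± 0.13. Ribosomal protein genes had a median of 0 (1 of 43 down, 0 adjusted over the list alone, adjusted p = 0.6). Growth genes had a median of 0.01, a mean of -0.04 and camera's direction down (2 of 11 up, also 2 adjusted over the list alone, adjusted p = 0.892).

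Between juvenile RFH and WT the 28 lists that did not pass had adjusted p-values from 0.0568 to 0.995. Lipid uptake genes had a median of 0.17 (adjusted p = 0.373), inflammatory genes 0.11 (adjusted p = 0.626), cholesterol synthesis genes 0.20 (adjusted p = 0.301) and complement genes 0.23 (adjusted p = 0.435). In 9 lists the median was above 0 and camera's direction down, among them the osteogenic, cell cycle and endothelial activation lists, and with cyclic loess the medians of the myofibroblast and ribosomal lists among them were -0.02. With only the 6 juvenile arrays fitted, 326 of 6765 genes were called, 245 up and 81 down, and 11 lists passed.

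A probe set annotated to B2M, chosen after its values were seen, averaged 9.57 ± 1.31 in adult RFH, 13.44 ± 0.94 in juvenile RFH and 11.51 ± 0.77 in WT arrays, and fell by 3.87 ± 0.67 (SE, limma adjusted p = 0.00412), while the brightest B2M probe set had a difference of 0.04 (adjusted p = 0.83). A probe set annotated to OAZ1, also chosen after its values were seen, fell by 4.02 ± 0.67 (limma adjusted p = 0.00334), and the brightest OAZ1 probe set had a difference of 0.18 (adjusted p = 0.356). Both may read an erythroid transcript, as a hypothesis. Over the 10 arrays centred on their groups, the first followed the mean of the 4 measured erythroid markers with Pearson r = 0.893 and the second with r = 0.883 (exact permutation p = 0.00463 for each over 864 permutations, 0.00463 adjusted over both). Spearman's rho was 0.842 for each (exact permutation p = 0.00579, 0.00579 adjusted), and without the 2 arrays farthest from the median r was 0.852 and 0.862. None of the 4 markers is on another list, and 1, HBB, lay above the median of all genes in WT arrays. HBB, the most abundant, averaged 9.25 in adult RFH, 9.65 in juvenile RFH and 9.87 in WT arrays. It did not follow the group pattern.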
